A study of Homo sapiens with 6 samples.

How the data were processed

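Expression was measured in 6 arrays of MCF10A cells with ErbB2, 3 labelled RB-proficient and 3 labelled RB-deficient, grown for 7 days in 3-D culture. Per the labels' protocols, cells and matrix were collected together in RNA-STAT-60, total RNA was extracted and amplified with the WT-Ovation Pico system, and the product was labelled with biotin, with 1 sample per array. The matrix was thus lysed with the cells. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.1. The summarisation, background correction and normalization between arrays are not given in the sources used here.

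The deposited values were intensities on a linear scale, 1 per probe set and array, as made by the authors, from 3.53e-05 to 7075. The column medians differed between arrays, so no common median had been set over all probe sets. The design written before the data were examined took log2 values as likely and gave the rule for linear ones, which was applied: each array was scaled to a common median, values under 1 were set to 1, and log2 was taken. A value of 0 on the log2 scale is therefore the floor. Values at the floor have no order, and differences of dim genes depend on it. Detection calls were not used here, so whether a probe set lay above background is unknown.

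Gene names came from the platform annotation supplied with the data. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed, and only those with 1 symbol entered the tests. Of these, 19429 matched a gene in the RefSeq table by gene number, and 0 symbols changed by that. Of several probe sets of a gene, the one with the highest mean over all 6 arrays was used, which mattered for 769 of the 18417 genes. No genome was used, and no coordinates are given.

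The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), with p-values adjusted by the Benjamini-Hochberg method over all 18417 genes and a threshold of 0.05. No date or batch is given in the labels used here. Same-numbered arrays of the groups did not deviate together, so no pairing was used. All 6 arrays held different values, and none was counted as a duplicate.

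Before the data were examined, 39 gene lists with 840 symbols were fixed, of which 757 were measured. They covered the cell cycle, E2F and p53, ERBB and ERK signalling, epithelial, mesenchymal, matrix and lineage genes, metabolism, stress, interferon and developmental pathways, and markers of fibroblasts, endothelium and leukocytes. The list of mitochondrial genome transcripts had 0 measured members, so 38 lists were tested. The test was limma's camera with a preset correlation of 0.01 and adjustment over the lists, beside camera with an estimated correlation and fry. Each list median was also placed among 10000 random lists of the same size matched on mean expression in 20 bins.

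Genes named in the text followed a rule fixed at the same time. It took RB1, RBL1, RBL2, ERBB2 and EGFR in any case. It took up to 12 genes past the threshold per direction, with no overlap between groups and ranked by size, filled up to 6 by unadjusted p where fewer passed. Symbols of uncharacterised, non-coding, olfactory and keratin-associated genes were left out of that part. It also took up to 4 members with the smallest p of each list that passed, and at most 2 of any other list. Other genes are marked as chosen after their values were seen.

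The fit was tested on simulated data for this comparison, with 18417 genes, 200 of them changed, in 10 runs. It recovered 0% of 2-fold, 1.4% of 4-fold, 28.4% of 8-fold and 69% of 32-fold changes, and a mean of 1.1 of 50.5 calls per run was false. The simulated noise was normal and independent between genes, with a pooled SD for both groups and no floor. These rates therefore do not cover the unequal spread of the groups, floored values or correlation between genes in the real arrays. Camera with the preset correlation recovered 20 of 20 simulated lists of 30 genes with 0 false lists, on data simulated without correlation between genes, each list lowered by 1 on the log2 scale.

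Alternatives fixed beforehand were quantile normalization, centring on each array's gene median, filters on the dimmest 25% and 50% of genes, the mean of a gene's probe sets, all probe sets in the adjustment, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, a floor of 16, limma's treat against a 1.2-fold change, camera with an estimated correlation, and fry. An offset of 16 added before log2 in place of the floor, the omission of the arrays labelled RB-deficient 1 and 2, and the values without scaling were added after seeing the data.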

Results

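Gene expression was measured on single-channel arrays in MCF10A cells, an established non-tumorigenic human mammary epithelial line, in the version that the series names with ErbB2, a receptor tyrosine kinase. The cells were grown in 3-D culture in a reconstituted basement membrane for 7 days. The labels gave 3 arrays of RB-proficient cells and 3 arrays of RB-deficient cells, so the design compared these cells by the state of RB, the retinoblastoma protein that restrains E2F transcription factors. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Median deposited intensities were 26.9, 27.1 and 24.2 in RB-proficient arrays 1 to 3, and 21.4, 26.8 and 28.0 in the arrays labelled RB-deficient 1 to 3. All differences are on the log2 scale, RB-deficient minus RB-proficient, with n = 3 per group.

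RB1, the gene that encodes RB, was read by probe set 7969017 and gave log2 intensities of 7.01, 5.77 and 7.65 in the RB-proficient arrays and 3.45, 5.09 and 6.04 in the arrays labelled RB-deficient. The mean difference was −1.95 (SE 0.76, 3.87-fold lower), with an adjusted p of 0.302 in limma's test, so RB1 did not pass, and the RB1 log2 difference was −1.25 without the array labelled RB-deficient 1. The array labelled RB-deficient 3 lay above RB-proficient array 2, so RB1 did not separate the 2 groups, and every direction given here rests on the labels. The sample titles carry the tags miNS and miRB for the 2 groups, which the labels do not spell out, so whether the RB1 transcript itself was targeted is left open. RBL2, a related pocket protein, was 2.22-fold lower (difference −1.15, SE 0.50, adjusted p 0.358), and each of its values in the arrays labelled RB-deficient lay below each RB-proficient value. RBL1, another pocket protein, differed by −0.58 (SE 0.61, adjusted p 0.686), and by −1.09 to −0.22 with single arrays left out. ERBB2 had means of 5.25 ± 0.33 (SD) in the RB-proficient arrays and 3.95 ± 0.26 (SD) in the arrays labelled RB-deficient. The ERBB2 difference of −1.31 (SE 0.48) had an adjusted p of 0.288, and its partner receptor EGFR differed by −0.99 (SE 0.52, adjusted p 0.431).

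**Figure D1:**
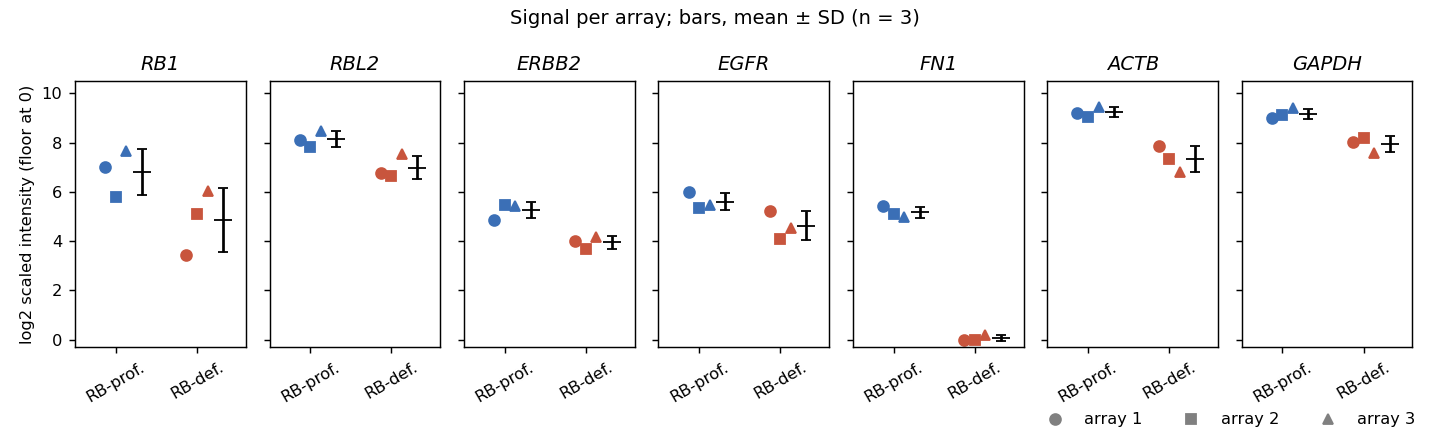
Log2 scaled intensity (y axis, floor at 0) of 7 genes in each of the 6 arrays, with RB-proficient arrays in blue and arrays labelled RB-deficient in red; the symbol gives the array number and black bars show mean ± SD (n = 3). RB1 overlaps between the groups, FN1 lies between 0 and 0.21 in the arrays labelled RB-deficient, and ACTB and GAPDH lie lower there in all 3 arrays.

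FN1, which encodes the matrix glycoprotein fibronectin, fell in the arrays labelled RB-deficient and was the only one of 18417 genes to pass an adjusted p of 0.05 with the main settings, which include a floor of 1, no filter on dim genes, all 6 arrays and limma's default eBayes. That count depends on the settings: 61 genes passed with eBayes with trend and robust, 58 with a floor of 16 and 193 with an offset of 16. Gene lists for glycolysis, fatty acid synthesis, cholesterol synthesis, autophagy, epithelial junctions and the pocket protein and E2F family were lower as groups by camera's preset test, and no list was higher. The 6 list calls were not kept with an estimated correlation between genes, where the adjusted p was 0.670 for each of them, and the reference genes ACTB and GAPDH were lower in the same arrays. Lists for DNA replication and mitosis, whose genes include many E2F targets, had no common direction in the 3 arrays labelled RB-deficient.

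FN1, probe set 8058765, had values of 5.43, 5.10 and 4.98 in the RB-proficient arrays and of 0, 0 and 0.21 in the arrays labelled RB-deficient, where 0 is the floor. The fitted difference was −5.10 (SE 0.46, 95% interval −6.14 to −4.06), with an adjusted p of 0.0186 in limma's test. Its size depends on the floor: with a floor of 16 in place of 1 the difference was −1.17 and the call was lost (adjusted p 0.0741). The floor also set the spread of FN1 in the arrays labelled RB-deficient (SD 0.12), which enters the SE, the interval and the p. The call was lost under 9 of 17 alternative settings, among them quantile normalization (adjusted p 0.127) and the omission of any single array except RB-deficient 3 (adjusted p 0.0512 to 0.299).

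The genes with the next smallest p-values did not pass with the main settings. GSTA5, a glutathione S-transferase, differed by −4.08 (SE 0.58). ARF1, a small GTPase that recruits coat proteins to the Golgi, differed by −3.95 (SE 0.59), from 7.57 ± 0.09 (SD) to 3.62 ± 1.01 (SD). KRT31, a hair keratin, differed by −3.70, FAM32A by −3.59 and CREB5, a cAMP response element binding protein, by −3.22. Each of these 5 had an adjusted p of 0.166, and ARF1 passed in 4 alternative settings (adjusted p 0.00875 with the offset of 16). GSTA5, KRT31 and CREB5 reached the floor in at least 1 array labelled RB-deficient. In the other direction the smallest adjusted p was 0.206, shared by RANBP3L (difference 3.03, SE 0.54), ADGRL4 (2.64, SE 0.49), LRRC19 (3.04, SE 0.59), STOX1 (2.62, SE 0.52), IL2 (2.94, SE 0.58) and PTPRD, a receptor-type tyrosine phosphatase, which was 5.67-fold higher (SE 0.51). The signals of ADGRL4, an adhesion receptor, and IL2, a T-cell cytokine, averaged 0.87 and 0.21 in the RB-proficient arrays, close to the floor. Sizes of dim genes depend on the floor: of 100 named genes besides RB1, the difference moved by over 1.5 times for 51 with the offset of 16 and for 30 with the floor of 16. Genes below that floor in all arrays, such as CREB5, had no difference there and are not in the latter count. STOX1 passed with the offset of 16 (adjusted p 0.0448) and RANBP3L with a floor of 16 (adjusted p 0.0358). All RB-proficient values of RANBP3L (2.97, 1.46 and 1.90) lay below that floor, so that group then had no spread and the pass rests on it.

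At an unadjusted p under 0.05, limma gave 525 genes higher and 1996 lower, where chance gives 920.9 in all. Without RB-proficient array 3 these counts were 268 and 984, and without the array labelled RB-deficient 3 they were 984 and 2907. By limma's treat against a 1.2-fold change, 0 genes were higher and 1 was lower. The 3 values of each group did not overlap for 4122 genes, which is 22.38% of those tested where chance gives 10%, and 2810 of them were lower in the arrays labelled RB-deficient. The median difference over all genes was −0.21, and it was −0.09 after quantile normalization and −0.07 after centring each array. With centring, 32.55% of the genes at an unadjusted p under 0.05 were higher, against 20.83% without.

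The arrays labelled RB-deficient varied more than the RB-proficient ones. The median SD of a gene was 0.84 in the former and 0.40 in the latter. Across genes, which are not independent replicates, RB-proficient arrays correlated with each other at Pearson's r of 0.90 to 0.92 and arrays labelled RB-deficient at 0.67 to 0.75. The array labelled RB-deficient 3 correlated at 0.83 to 0.88 with the RB-proficient arrays. Genes at the floor made up 4.71%, 1.62% and 0.684% of the genes in the arrays labelled RB-deficient 1 to 3, and 0.326% to 0.684% in the RB-proficient arrays. ACTB, the cytoskeletal actin used as a reference gene, had means of 9.24 ± 0.21 (SD) and 7.33 ± 0.52 (SD), a difference of −1.92 (SE 0.50, adjusted p 0.213). ACTB passed over all genes with trend and robust (adjusted p 0.0464) and with the offset of 16 (0.0393). GAPDH differed by −1.23 (SE 0.47, adjusted p 0.302) and passed in 0 settings. Both were lower in all 3 arrays labelled RB-deficient and in all 19 alternative settings, and both were chosen after their values were seen.

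**Figure D2:**
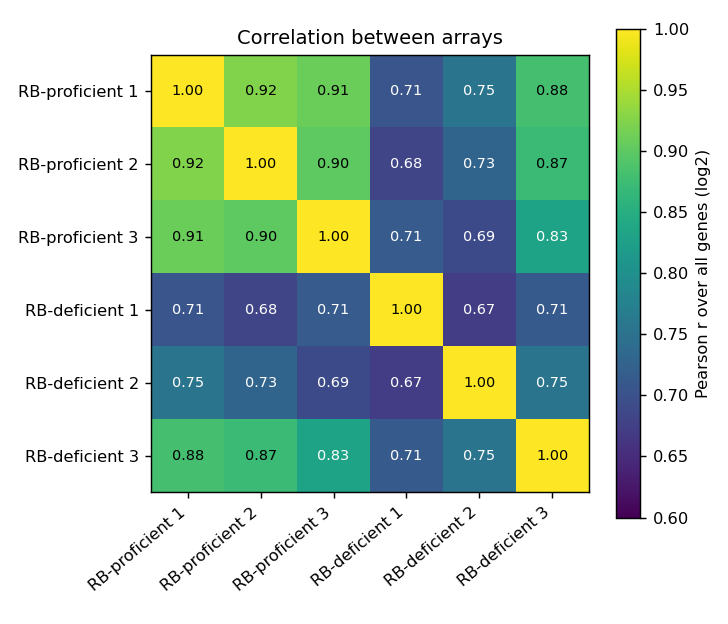
Pearson's r across all genes for each pair of the 6 arrays, on log2 scaled intensities, with brighter cells for higher r. Pairs of RB-proficient arrays lie at 0.90 to 0.92, pairs labelled RB-deficient at 0.67 to 0.75, and the array labelled RB-deficient 3 at 0.83 to 0.88 with RB-proficient arrays.

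Glycolysis genes were lower as a group in the arrays labelled RB-deficient. Of 17 measured members 16 were lower, 10 of them with no overlap between the groups, and the list median was −1.23, which is −1.02 relative to the median of all genes. TPI1, triosephosphate isomerase, was 8.40-fold lower (SE 0.49 on the log2 scale), and its difference of −3.07 became −1.54 with the mean of its probe sets. PKM, the pyruvate kinase of the last step, was 7.52-fold lower (SE 0.51), SLC2A1, the glucose transporter GLUT1, 4.65-fold lower (SE 0.52) and ALDOA, an aldolase, 4.53-fold lower (SE 0.56). Adjusted over the list alone, 5 members passed (these 4 and GPI), and adjusted over all genes 0 passed with the main settings. All 5 passed over all genes with the offset of 16, and PKM (adjusted p 0.000832) and TPI1 (adjusted p 0.0253) also with trend and robust. Camera's preset test gave the list an adjusted p of 9.64e-05, and the p with an estimated correlation was 0.122 before adjustment. The reference gene GAPDH is itself a member, and its own difference is the list median, which is −1.27 over the 16 other members. The list median was −1.01, −1.69 and −1.23 in the arrays labelled RB-deficient 1, 2 and 3. The separate lists of hypoxia response genes (19 measured, median −0.70, adjusted p 0.347) and oxidative phosphorylation genes (34 measured, median −0.26, adjusted p 0.379) did not pass.

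Lipid synthesis genes were also lower in these arrays. All 10 measured genes of fatty acid synthesis were lower, with a list median of −1.16 (−0.95 relative to all genes) and an adjusted p of 0.00881 by camera's preset test. With an estimated correlation the p was 0.184 before adjustment. FASN, the fatty acid synthase, was 10.2-fold lower (SE 0.89), ACSS2, an acetyl-CoA synthetase, 7.15-fold lower (SE 0.67), ACLY, the ATP citrate lyase, 5.32-fold lower (SE 0.80) and ACACA, the acetyl-CoA carboxylase, 3.94-fold lower (SE 0.62). Without the array labelled RB-deficient 1 the difference of ACLY went from −2.41 to −1.47, and with the offset of 16 that of FASN was −1.78 and that of ACSS2 −1.63. The list medians in the arrays labelled RB-deficient 1 to 3 were −1.49, −1.37 and −0.90, and without RB-proficient array 3 the median was −0.68 and the call was lost. The 4 genes passed when adjusted over the list alone and 0 passed over all genes with the main settings. Of 18 cholesterol synthesis genes 15 were lower, with a list median of −0.75 (−0.54 relative to all genes) and an adjusted p of 0.0304, against a p of 0.177 before adjustment with an estimated correlation. FDPS, the farnesyl diphosphate synthase, differed by −2.29 (SE 0.60), DHCR7 by −1.88 (SE 0.56), CYP51A1 by −1.58 (SE 0.56) and STARD4, a sterol carrier, by −1.43 (SE 0.51). The list medians in the 3 arrays were −1.21, −0.72 and −0.57. The cholesterol call was lost in 8 of 19 alternative settings. Among these were the omission of RB-proficient array 3, of RB-deficient array 1 and of RB-deficient array 3. For cholesterol synthesis 0 members passed adjusted over the list alone or over all genes with the main settings, and FDPS passed over all genes with the offset of 16 (adjusted p 0.0418). ACTB and GAPDH were lower in the same arrays.

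Autophagy genes were lower as a group, 14 of 16, with a list median of −1.10 (−0.89 relative to all genes) and an adjusted p of 0.00673 by camera's preset test. For autophagy the p was 0.174 before adjustment with an estimated correlation. The list medians in the arrays labelled RB-deficient 1 to 3 were −1.33, −1.40 and −0.57, and the median over settings ran from −1.72 to −0.57. SQSTM1, the cargo receptor p62, was 3.99-fold lower (SE 0.46), ATG7, which activates ubiquitin-like conjugation in autophagosome formation, 4.54-fold lower (SE 0.59) and LAMP1, a lysosomal membrane protein, 3.33-fold lower (SE 0.49). These 3 passed adjusted over the list alone, ATG16L1 (difference −1.79, SE 0.68; −1.16 without the array labelled RB-deficient 2) did not, and 0 members passed over all genes with the main settings. SQSTM1 passed over all genes with trend and robust (adjusted p 0.0422), the floor of 16 (0.0415) and the offset of 16 (0.0307), and LAMP1 with trend and robust (0.0443) and the offset (0.0417). Epithelial junction and polarity genes were lower for 22 of 27 members, with a list median of −0.94 (−0.73 relative to all genes) and an adjusted p of 0.0126, against a p of 0.0718 before adjustment with an estimated correlation. Their list medians in the 3 arrays were −1.11, −0.97 and −0.40. RAB25, a small GTPase of epithelial recycling endosomes, was 4.69-fold lower (SE 0.47) and JUP, the junctional protein plakoglobin, 4.28-fold lower (SE 0.47), and these 2 passed adjusted over the list alone. ESRP2, an epithelial splicing regulator, differed by −2.01 (SE 0.68), or −1.34 without the array labelled RB-deficient 1, and DSG2, a desmosomal cadherin, by −1.41 (SE 0.48), and 0 junction genes passed over all genes with the main settings. RAB25 passed over all genes with trend and robust (adjusted p 0.0422), the floor of 16 (0.0415) and the offset of 16 (0.0249), and JUP with the offset (0.0309). ACTB and GAPDH were lower in the same arrays as these lists.

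All 13 measured members of the pocket protein and E2F family were lower, with a list median of −0.78 (−0.57 relative to all genes) and an adjusted p of 0.0304 by camera's preset test. The p with an estimated correlation was 0.119 before adjustment. The list medians in the 3 arrays were −1.30, −1.30 and −0.61. Among random lists matched on mean expression, the list median of −0.78 lay at percentile 2.65, just inside their central 95% (−0.788 to 0.371). The median of each other called list lay below the central 95% of its own matched lists. So did the medians of nucleotide synthesis, basement membrane and integrins, antigen processing, and matrix proteases and inhibitors, which were not called. This placement therefore does not set the called lists apart. RB1, whose protein names the groups, had the smallest p of the members of the pocket protein and E2F list. Besides RB1 and RBL2, E2F6 differed by −1.36 (SE 0.62) and E2F8 by −1.53 (SE 0.70; −0.95 without the array labelled RB-deficient 1), which are repressor members of the E2F family. For this list 0 members passed adjusted over the list alone (smallest adjusted p 0.175) or over all genes. ACTB and GAPDH were lower in the same arrays. Without the arrays labelled RB-deficient 1 and 2, only the glycolysis list kept its call among the 6, and the pocket protein and E2F list was called in 10 of 19 alternative settings.

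**Figure D3:**
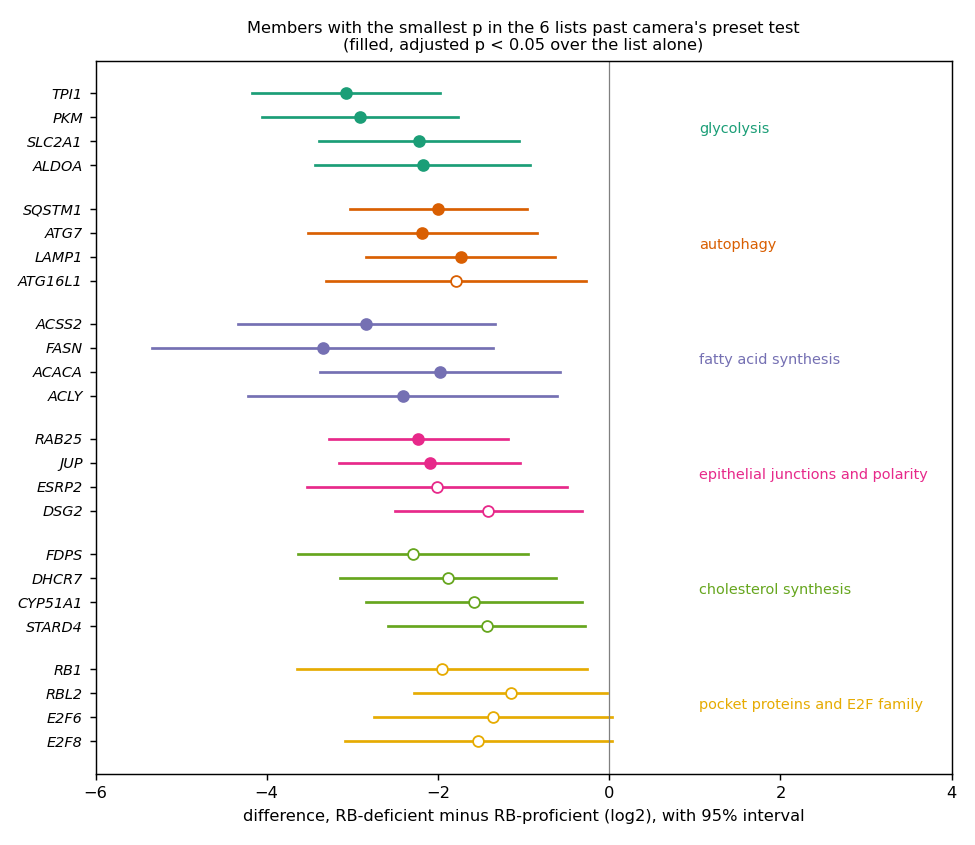
Difference in log2 intensity (x axis, RB-deficient minus RB-proficient) with its 95% interval for the 4 members with the smallest p in each of the 6 lists that passed camera's preset test. Filled points passed adjusted over the list alone; TPI1 lies at −3.07 and FASN at −3.35, and 0 of the 24 members passed over all genes with the main settings.

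The cell-cycle lists did not move one way. For G1/S and DNA replication, 30 of 45 genes were lower, the list median was −0.31 and the adjusted p was 0.600, and the list was called only without the array labelled RB-deficient 1 (adjusted p 0.0459). The list's median was 0.30, −1.14 and −0.46 in the arrays labelled RB-deficient 1, 2 and 3. POLA2, a subunit of the polymerase alpha-primase complex, differed by −3.06 (SE 0.87) and MCM5, of the replicative helicase, by −2.25 (SE 0.69; −1.48 without RB-proficient array 3), and neither passed adjusted over the list alone (adjusted p 0.211). For G2/M and mitosis, 25 of 39 genes were lower, the list median was −0.19, the adjusted p was 0.935, and the medians in the 3 arrays were 0.91, −0.90 and −0.36. Among its members KIF20A, a mitotic kinesin, differed by −2.43 (SE 0.81) and BUB1, a checkpoint kinase, by −1.89 (SE 0.64). DNA repair and checkpoint genes had a median of −0.23 (adjusted p 0.927), with CHEK2 at −3.26 (SE 0.88) and XRCC2 at 2.37 (SE 0.82), or 1.38 without the array labelled RB-deficient 1. POLA2 and CHEK2 were at the floor in the array labelled RB-deficient 1, so the size of these 2 differences depends on the floor. Nucleotide synthesis genes were lower for 15 of 19 members (median −0.93, adjusted p 0.181), with ATIC at −2.33 (SE 0.66). The nucleotide synthesis median was −0.28, −1.42 and −0.34 in the arrays labelled RB-deficient 1 to 3. Replication-dependent histones (median −0.47, adjusted p 0.985), chromatin and polycomb factors (median −0.06, adjusted p 0.550), CDK inhibitors and D-type cyclins (median 0.04, adjusted p 0.927) and p53 targets (median −0.47, adjusted p 0.380) did not pass either. CDK4 differed by −2.05 (SE 0.71) and CDKN1A, the inhibitor p21, by −2.16 (SE 0.89), or −1.05 without the array labelled RB-deficient 1.

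Among lists for signalling, matrix and cell identity, 0 passed. ERBB receptors and ligands had a median of −0.36 (adjusted p 0.758) and included ERBB3 at −2.89 (SE 1.03), which was −1.74 without the array labelled RB-deficient 1 and overlapped between the groups. ERK pathway output had a median of −0.58 (adjusted p 0.550), immediate early genes of −0.71 (adjusted p 0.204), TGF-beta and BMP targets of −0.45 (adjusted p 0.439), YAP targets of −0.57 (adjusted p 0.330), Notch pathway genes of 0.30 (adjusted p 0.668) and Wnt pathway genes of −0.63 (adjusted p 0.474). The immediate early median was 0.03, −1.34 and −0.53 in the arrays labelled RB-deficient 1 to 3. Mesenchymal genes, which include FN1, had a median of −0.21 (adjusted p 0.882), with the cadherin CDH2 at −2.09 (SE 0.60). Basement membrane and integrin genes had a median of −0.89 (adjusted p 0.204) and matrix proteases and inhibitors of −0.65 (adjusted p 0.242). Basal and myoepithelial markers had a median of −0.70 (adjusted p 0.330), luminal markers of 0.18 (adjusted p 0.570) and squamous differentiation genes of −0.31 (adjusted p 0.875). The basal and myoepithelial median was 0.16, −1.61 and −0.71 in the arrays labelled RB-deficient 1 to 3.

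Single members of these lists were lower when adjusted over the list alone, though with the main settings FN1 alone passed over all genes. ITGB4, an integrin subunit of hemidesmosomes, differed by −2.29 (SE 0.52), and TIMP1, an inhibitor of matrix metalloproteinases, by −3.90 (SE 0.72), or −1.96 with the offset of 16. ID1, a BMP target, differed by −2.45 (SE 0.56), the YAP target NT5E by −3.21 (SE 0.80) and the Notch ligand JAG1 by −2.56 (SE 0.65). NT5E and IFIT1, an interferon-induced gene, reached the floor in at least 1 array labelled RB-deficient, so the size of their difference depends on the floor. Of 30 squamous differentiation genes 17 were lower and 13 higher, and 5 passed adjusted over the list alone, all lower, S100A9 (−2.39, SE 0.53), KLK10 (−2.11, SE 0.51), KRT1, KRT4 and PI3, of which the last 3, like GPI among the glycolysis genes, were chosen after their values were seen. IFIT1 differed by −2.97 (SE 0.66) and the fibroblast marker FBLN1 by −2.39 (SE 0.61). Members named by the same rule that were higher, XRCC2 included, did not pass over the list alone. COL6A3, a collagen, differed by 1.11 (SE 0.48) and the progesterone receptor PGR by 1.63 (SE 0.49). The histone H2BC3 differed by 1.59 (SE 0.53) and H3C11 by 1.31 (SE 0.51). The others were the DNA methyltransferase DNMT1 (1.25, SE 0.56), TIE1 (1.102, SE 0.47) and PTPRC (1.38, SE 0.58; 0.88 without RB-proficient array 1). In all, 27 list members in 13 lists passed adjusted over the list alone, and 0 of them were higher. TIMP1, ITGB4, ID1, JAG1, S100A9, KRT1 and KRT4 passed over all genes with the offset of 16 (adjusted p 0.0393 to 0.0492), TIMP1 and KRT1 also with trend and robust, and ITGB4 with the floor of 16.

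The remaining lists did not pass with the main settings. Ribosomal proteins had a median of −0.48 with 29 of 32 members lower (adjusted p 0.0571), and were called lower in 9 of 19 alternative settings, among them the offset of 16 (adjusted p 0.00186) and no scaling between arrays (0.0149). Their p with an estimated correlation was 0.571 before adjustment, and without the array labelled RB-deficient 3 the preset test gave an adjusted p of 0.577. RPL18 passed over all genes with trend and robust (adjusted p 0.0356) and the offset (0.0393), RPS9 with trend and robust (0.0422) and RPS15, chosen after its values were seen, with the offset (0.0393). Nucleotide synthesis and immediate early genes were called in 3 alternative settings each, oxidative phosphorylation in 2, and basement membrane and integrins, matrix proteases and basal markers in 1 each. Interferon-stimulated genes had a median of −0.55 (adjusted p 0.347), antigen processing genes of −0.94 (adjusted p 0.347) and NF-kB and inflammatory cytokine genes of 0.10 (adjusted p 0.674). The unfolded protein and amino acid response had a median of 0.02 (adjusted p 0.927) and apoptosis regulators of −0.41 (adjusted p 0.347). Markers of other cell types gave medians of 0.32 for fibroblasts (adjusted p 0.668), 0.06 for endothelium (adjusted p 0.487) and 0.29 for leukocytes (adjusted p 0.380). Of the 32 lists that did not pass, 11 had a median that changed sign when some single array was left out: G1/S and DNA replication, G2/M and mitosis, DNA repair, chromatin factors, CDK inhibitors, mesenchymal genes, luminal markers, NF-kB genes, the unfolded protein response, and fibroblast and endothelial markers. The median was above 0 and the mean below it for CDK inhibitors and D-type cyclins, luminal markers, NF-kB genes, the unfolded protein response, the Notch pathway and fibroblast markers, and camera's direction was up for all of these but the unfolded protein response. For chromatin factors the median and mean were below 0 and camera's direction was up, since camera compares a list with the other genes. By fry, which tests a list on its own, 0 lists passed (smallest adjusted p 0.0557) and 14 had an unadjusted p under 0.05. With an estimated correlation, 0 lists had an unadjusted p under 0.05.

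**Figure D4:**
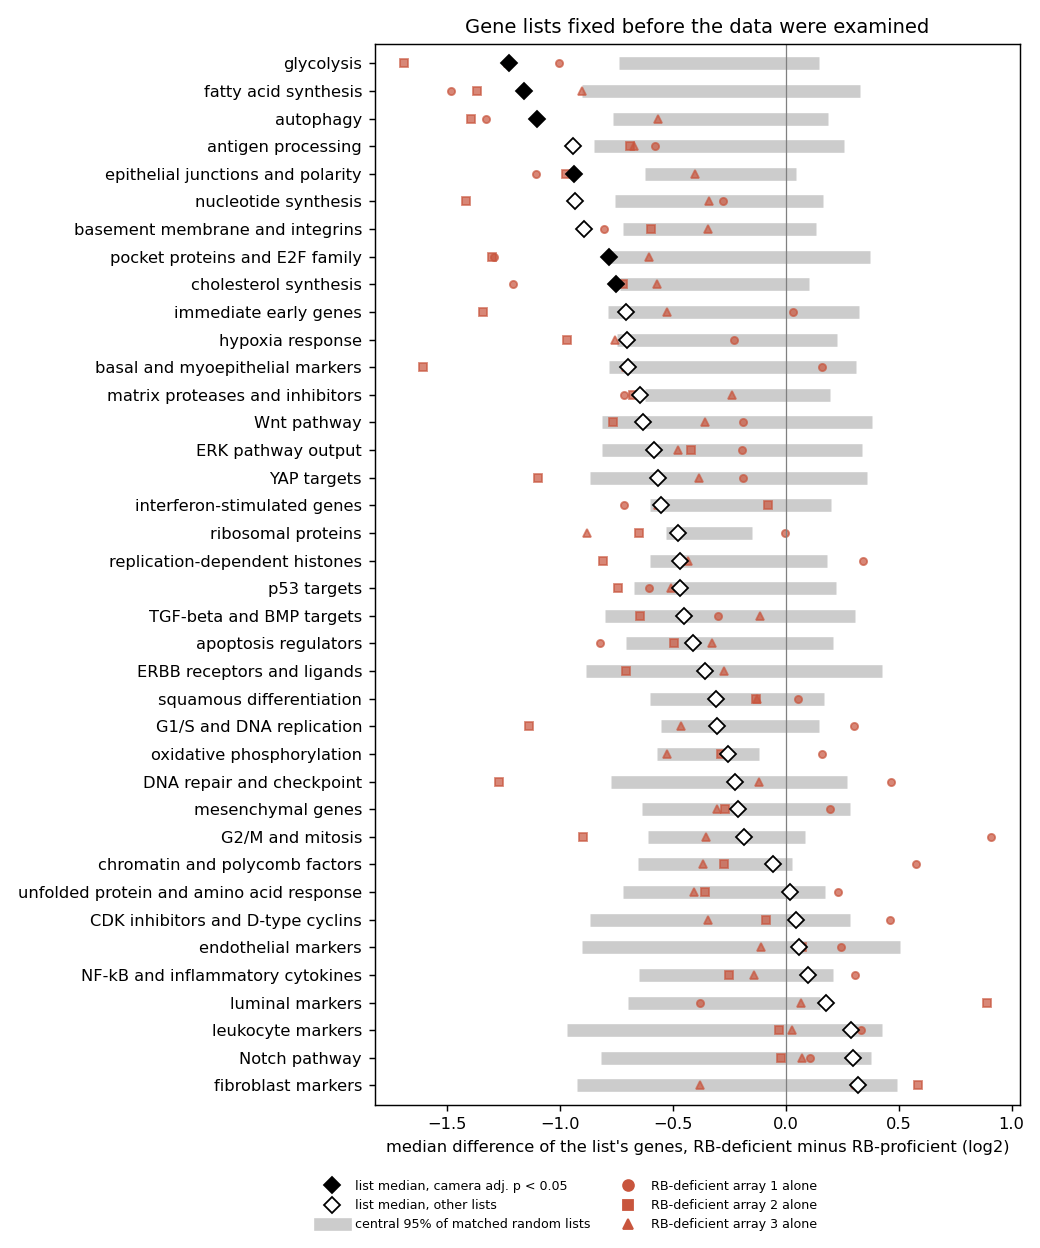
Median difference of each of the 38 tested lists (x axis, log2, RB-deficient minus RB-proficient) as diamonds, filled where camera's preset test passed, with the central 95% of random lists matched on mean expression in grey and each array labelled RB-deficient taken alone in red. Glycolysis lies lowest at −1.23, below its grey bar in all 3 arrays, while the medians of G2/M and mitosis run from −0.90 to 0.91.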

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

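The offset of 16, the omission of the arrays labelled RB-deficient 1 and 2 and the values without scaling were chosen after seeing the data; the other settings were planned. The gene counts were sensitive to the floor and to the model of the spread, and the cause was not tested; genes named here outside the rule were chosen after their values were seen. Against 0 genes higher and 1 lower (also the count changed at least 2-fold), quantile normalization, the 25% dim filter and all probe sets in the adjustment gave 0 lower and 0 changed at least 2-fold, and the 50% dim filter gave 4 lower (ARF1, DHX30, TPI1 and PABPC4), all at least 2-fold. Both filters remove FN1 by construction. eBayes with trend and robust gave 61 lower, all at least 2-fold. A floor of 16 gave 10 higher and 48 lower, 51 of them at least 2-fold, with 961 genes of zero spread. Of its 58 calls, 14 had zero spread in the arrays labelled RB-deficient and 5 in the RB-proficient ones. ADGRL4, IL2 and CREB5 had no value with that floor, since they lay below it in all arrays. An offset of 16 gave 7 higher and 186 lower, 193 at least 2-fold, and shared 59 of the 61 genes called with trend. Without the arrays labelled RB-deficient 1 and 2 there were 0 lower and 0 changed at least 2-fold; the lone array left is then assumed to vary like the RB-proficient ones. Leaving out each array in turn gave 0 to 4 genes lower or changed at least 2-fold, with the highest count without RB-deficient 3 (FN1, OLFML2A, GNA12 and PER2), and 3 to 10 lists lower, with 3 without RB-proficient 3 and 10 without RB-deficient 1. Without RB-deficient 1, 4 of the 6 main list calls were kept, and the rest of the 10 were new. Against 6 lists lower, the dim filters gave 3 (25%) and 2 (50%), all probe sets 11, and camera with an estimated correlation and fry 0. Array weights gave 4 lists lower, with 3 of the 6 kept. Glycolysis was called in 19 of 19 camera settings with the preset correlation, autophagy in 18, junctions in 16, fatty acid synthesis in 15, cholesterol synthesis in 11 and the pocket protein and E2F list in 10. RB1 stayed lower in all 19 settings, from −2.54 to −0.77, and passed in 0 (adjusted p 0.123 to 0.740). RBL1 turned to 0.43 without the arrays labelled RB-deficient 1 and 2. For the named genes besides RB1, 1780 of 1830 values kept their direction and side of the threshold, 40 became calls, 9 lost the call and 1 reversed. Deviations of same-numbered arrays correlated at −0.12, 0.07 and −0.11, so the numbers do not pair them, and not every array correlates best with its own number; with the replicate block 1 gene and 4 lists were lower. Signal over background could not be assessed, which limits the dim genes most.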

Other observations

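The tests of the 2 gene lists of the next paragraph, of the glycolysis list, of the label of the array RB-deficient 3 and of FN1 were chosen only after the result was seen, as were the genes named in the next paragraph and the offset of 16; the counts over splits were planned.

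Genes of the early secretory pathway and of translation stood among those with the smallest p. With an offset of 16, 193 genes passed, 96.37% of them lower in the arrays labelled RB-deficient. They included ARF1 (difference −2.80, SE 0.35), the coat protein COPA (−2.12, SE 0.36), the Golgi exchange factor GBF1 (−2.12, SE 0.36) and the cargo receptor SURF4 (−2.39, SE 0.38). They also included the elongation factor EEF2 (−2.45, SE 0.40), the poly(A)-binding protein PABPC4 (−2.39, SE 0.38), PKM (−2.86, SE 0.37) and STAT6 (−2.48, SE 0.37). The hypothesis that the rest of these groups is lower too was tested, with the main settings, on lists without the genes that drew notice and without every gene called in any setting, which took 2 and 4 further genes out. The lists were drawn up after the calls were seen, so the themes themselves are not independent of the data. Of the 35 genes left of the early secretory pathway 32 were lower, with a median of −1.03, and the list lay at percentile 0.01 of 10000 matched lists, the smallest they can give. Its camera p was 6.94e-05 with the preset correlation and 0.150 with an estimated one. Of the 31 tRNA synthetases and translation factors left 30 were lower, with a median of −0.91, at percentile 0.01 as well. The p for this list was 4.44e-06 with the preset and 0.205 with an estimated correlation. LMAN2 (−2.08, SE 0.57), ARF3 (−2.09, SE 0.63), KARS1 (−1.68, SE 0.54) and AARS1 (−1.99, SE 0.64) had the 2 smallest p-values of their list among the genes left. Lower secretory and translation transcripts may go with the RB label, or with the lower ACTB and GAPDH signal of the same arrays, which these tests do not separate.

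Glycolysis genes, the lowest of the 38 lists by median and tested further for that reason, were lower in all 3 arrays labelled RB-deficient. By mean difference fatty acid synthesis was lower (−1.48 against −1.34). A loss of signal that depends only on expression level predicts a median like that of matched lists, and the list lay at percentile 0.02 of 10000 such lists (median −1.23, central 95% from −0.75 to 0.14). RB-proficient arrays, each set against the mean of the other 2, lay at percentiles 0.37, 4.4 and 100 (medians −0.44, −0.39 and 0.86), so the members of this list also vary together where RB status is the same. One aberrant RB-deficient array predicts at most 1 median below the lowest of these by more than their SD of 0.73. The 3 arrays lay 0.568, 1.25 and 0.79 below it, so 2 exceeded that SD and the first did not. Taken alone, the 3 arrays lay at percentiles 0.63, 0.02 and 0.01 of their matched lists. The list was also called without any one of them (adjusted p at most 0.00936). The lower median was thus not confined to 1 array labelled RB-deficient. The criterion, set after the result was seen, asked for all 3 arrays to exceed the SD, so it does not decide about 1 aberrant array. RB-proficient array 1 also reached percentile 0.37. RB status, as the biological explanation that the design names, may account for the lower glycolysis signal. So may a difference in RNA quality that falls on particular transcripts, since ACTB was lower too. The test with an estimated correlation did not call the list, which does not bear on the cause.

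The array labelled RB-deficient 3 correlated best with RB-proficient arrays. Over the 200 genes that best part the other arrays, from 0 at the RB-proficient mean to 1 at the RB-deficient mean, its median position was 0.315, against 0.26, 0.185 and 0.003 for left-out RB-proficient arrays and 0.716 and 0.672 for the arrays labelled RB-deficient 1 and 2. In this array FN1 was 0.21, against 4.98 to 5.43 in the RB-proficient arrays, and the glycolysis median was −1.23. ACTB and GAPDH were lower in it than in each RB-proficient array. RB1, named before the data were examined, was 6.04 in it, within the RB-proficient values of 5.77 to 7.65. GNA12, OLFML2A and PER2 were 0 in the other 2 arrays labelled RB-deficient and 5.22, 4.98 and 4.69 in this one. That is closer to their RB-proficient means of 5.28, 6.29 and 5.75. These 3 genes were called in the fit without this array and not with all arrays in the main settings. That choice favours values near the RB-proficient ones here, so they do not count for a mislabelled array. FN1, the glycolysis list, ACTB and GAPDH were in turn picked with this array counted as RB-deficient, so they do not decide against a mislabelled array. FN1 was also called without this array (adjusted p 0.048 in limma's test), but so were the 3 genes that go the other way. All these genes except RB1 were chosen after their values were seen. The median position of this array exceeds that of the highest RB-proficient array by less than the SD of their positions (0.132), a criterion set after the value was seen. A mislabelled array and a milder RB-deficient array were thus not told apart, with 3 arrays per group too few to decide.

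FN1 lay near the floor in all 3 arrays labelled RB-deficient. Well-measured here means a log2 value of at least 4.5 in each RB-proficient array, without any detection call, and near the floor means at most 0.5. With independent drop-out of probe sets in each array, the shares near the floor (1.58%, 0.242% and 0.03% of 9911 well-measured genes) give 0.000115 genes near it in all 3 arrays. FN1 prompted this test and its values were known when the limits were set, and 0 other genes met them, so the count decides nothing about independent drop-out of probe sets in each array. A fault of FN1's single probe set shared between arrays and a loss of FN1 transcript with RB status stay open as well. With a floor of 16 the FN1 difference was −1.17 and the call was lost.

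The 6 arrays have 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene past the threshold and the highest of the other splits 0, so 1 of 10 splits had a count as large. For gene lists the real split gave 6 and the highest of the others 11, and 4 of 10 splits gave as many. Genes at an unadjusted p under 0.05 numbered 2521 in the real split and 922 in the highest of the others.

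Of 13837 probe sets without a single gene name, 0 passed in limma's test adjusted over them, and 1439 had an unadjusted p under 0.05.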
